A study of Mus musculus with 8 samples.

How the data were processed

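Gene expression was measured by bulk RNA sequencing in livers of male C57BL/6J mice, an inbred laboratory strain, at about 10 weeks of age. Per the labels, livers were snap-frozen, poly(A) RNA was captured with oligo(dT) beads, and TruSeq libraries were sequenced as single reads on an Illumina HiSeq instrument. The deposited table holds raw counts, that is whole numbers of reads per gene, for 55487 Ensembl genes, and the authors applied no normalization to them as far as the values show. Per the submitters' processing notes, the tools included FastQC, HISAT2 2.1.0, Subread and edgeR, with the mouse genome build GRCm38. The counting settings, the annotation release and whether strand was used in counting are not given in the sources used here. Reads that match close paralogs could therefore be split or discarded, and reads of overlapping antisense genes could not be told apart from those of their partners. This concerns Saa1 and Saa2, the haemoglobin genes, Acot1 and Acot3, and the Cyp4a and Cyp2a families, whose single-gene values are uncertain.

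The groups were taken from the treatment given in the labels: 4 libraries from mice given water (control) and 4 from mice given 17 mg of potassium sorbate, both 4 hours after gavage. Replicate numbers name libraries in accession order and pair nothing. The labels give no batch, cage, pairing or clock hour of collection, and the library numbering runs by group. Columns of the table were matched to samples by name, and 4 further per-sample columns matched no sample and were not used in any step. The labels speak of livers from mice but do not say that each library is a different animal, so the p-values measure the spread between these libraries. Within each group all pairs of libraries differed by far more than sampling noise (chi-square per gene from 25.1 to 241), so each library counted as 1 replicate.

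Total counts per library ran from 15773932 to 25844731. Of the 55487 genes, 31882 had a count of 0 in all 8 libraries. The filter filterByExpr of edgeR, with its count minimum of 10, kept 13312 genes, which held at least 99.88% of the counts in every library. Libraries were scaled by TMM factors, and CPM values, read counts relative to the scaled library sizes, were computed from them. The sorbate group was compared with the control group by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors of log2 fold changes were derived from the unshrunk coefficient and the quasi-likelihood F statistic. Principal components were computed on log2 CPM with a prior count of 2. Total counts, the percentage of counts in the 10 most abundant genes and the percentage from mitochondrially encoded transcripts were compared by exact permutation tests over 70 arrangements, two-sided, where the smallest p is 0.0286.

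Before the data were examined, 47 gene lists were fixed: 33 lists of pathways and of RNA quality, and 14 lists of cell type markers. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the 33 lists and over the 9 testable cell type lists separately. Camera with a correlation estimated from the data and the rotation test fry were run as alternatives. The camera test was also run on other splits of the libraries. Gene symbols come from the table. Coordinates come from GENCODE vM21 on GRCm38, the build named by the submitters, where 55227 of the 55487 gene identifiers and 13306 of the 13312 tested genes were found.

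The genes to be named were set by a rule before the data were examined. It takes the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold, with a mean of at least 1 CPM in a group and no overlap between the groups, leaving out predicted genes and pseudogenes. In each direction, places that stayed empty would have gone to the genes with the lowest p, which was not needed. From each list it takes up to 4 members with the lowest p among those past the threshold over all genes or over the list alone, or at most 2 as values if none passed. It always takes Hdac1, Hdac2, Hdac3, Hdac8, Tnf, Il1b, Il6, Ccl2, Nfkbia, Saa1 and Saa2. The rule gave 167 genes, of which a selection is printed. Genes named outside it are marked as chosen after their values were seen.

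The scripts were tested on simulated counts made from the means, dispersions and library sizes of these data for the comparison of sorbate with control, with 200 genes changed. Of the simulated changes, 10.8% of the 1.5-fold, 65.2% of the 2-fold and 92.4% of the 4-fold changes were called, none with the wrong sign, and 4.31% of the 116 calls were false among 13114 genes tested. With no gene changed, 0 genes were called. In this simulation 1.5-fold changes were thus mostly missed. The data gave 1656 calls, and the adjusted threshold is looser where more genes change, so recovery in the data may differ.

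The alternatives were DESeq2's size factors (edgeR's RLE), upper-quartile scaling, library size alone, no filter on low counts, a stricter filter (at least 10 counts in at least 4 libraries and a mean of at least 1 CPM), the DESeq2 1.42.0 Wald test, limma-voom with and without sample quality weights, edgeR with robust estimation, 1 surrogate variable (sva 3.50.0) as a covariate, leaving out the 10 most abundant genes, an adjusted p under 0.1, glmTreat against a 1.5-fold change, the 50 most abundant genes in place of 10, and leaving out each library in turn. Removal of the trends with exon length and GC content was added after seeing the data. It covered 13301 of the tested genes. Single-gene results for 2 list members are not reported here.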

Results

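The series holds 8 liver transcriptomes from male mice, 4 taken 4 hours after an oral gavage of water and 4 taken 4 hours after a gavage of 17 mg of potassium sorbate, the salt of a short unsaturated fatty acid used as a food preservative. The series title links sorbate to lysine sorbylation, an acyl mark placed by class I histone deacetylases (HDACs), and to inflammation genes, so the design poses 1 question: which liver transcripts differ between sorbate and water. Total counts per library were 20693506 ± 2018778 (SD, n = 4) in the control group and 20983509 ± 4116785 (SD, n = 4) in the sorbate group, which did not differ in an exact permutation test (p = 0.971, adjusted p = 0.971 over 3 measures). The 10 most abundant genes took 20.5% ± 0.564 of the counts in the controls and 19.4% ± 0.780 with sorbate (SD, n = 4; exact permutation p = 0.0571, adjusted p = 0.171). The share of the 50 most abundant genes differed by −4.90 percentage points with sorbate (exact permutation p = 0.0286, the smallest possible), and without sorbate 2 that of the 10 most abundant genes differed by −1.30 points (exact permutation p = 0.0286). Mitochondrially encoded transcripts took 5.21% ± 0.947 and 5.56% ± 1.32 (SD, n = 4; exact permutation p = 0.686, adjusted p = 0.971).

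Sorbate-treated livers had higher levels of clock-output and fatty acid oxidation genes, and lower levels of acute-phase and cholesterol synthesis genes. Of 13312 genes tested, 818 were higher and 838 were lower with sorbate, together 12.4% of the genes (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of these, 238 higher and 366 lower genes differed by at least 2-fold. The groups did not overlap in 753 of the higher and 648 of the lower genes. Among all tested genes 17.7% showed no overlap, where chance gives 2.86%. Scaling by library size alone gave 1300 higher and 550 lower genes, so that 70.3% of the calls were higher in place of 49.4%, and moved the median log2 fold change of all genes from −0.02 to 0.11. Camera called 14 of the 33 pathway and quality lists and 3 of the 9 cell type lists, and 0 lists with an estimated correlation, while fry called 7 higher and 2 lower pathway lists and 0 cell type lists. Log2 fold changes are relative to the TMM-scaled libraries.

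The first principal component held 53.6% of the variance. The sorbate libraries scored 21.9 to 37.8 on it and controls 1, 3 and 4 scored −49.1 to −42.1, but control 2 scored 15.4. This library stood apart from the other controls in several gene groups described below. Without control 2 the test called 2053 higher and 1915 lower genes. Leaving out another library lowered both counts: they were 481 and 492 without control 1, 332 and 357 without control 3, 390 and 406 without control 4, 432 and 428 without sorbate 1, 555 and 572 without sorbate 2, 410 and 370 without sorbate 3, and 367 and 366 without sorbate 4. With 1 surrogate variable as a covariate, 313 genes were higher and 293 lower. This variable was 0.471 in control 2, 0.0844 to 0.305 in the sorbate libraries and −0.532 to −0.365 in the other controls. It correlates with the group (0.588), so a smaller fold change or a call lost with it may come from treatment difference that it takes up. Sample quality weights, which gave control 2 the lowest weight at 0.309, led limma-voom to 1968 higher and 1944 lower genes. A test against a 1.5-fold change kept 80 higher and 122 lower genes, and a threshold of 0.1 gave 1337 and 1414.

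**Figure D1:**
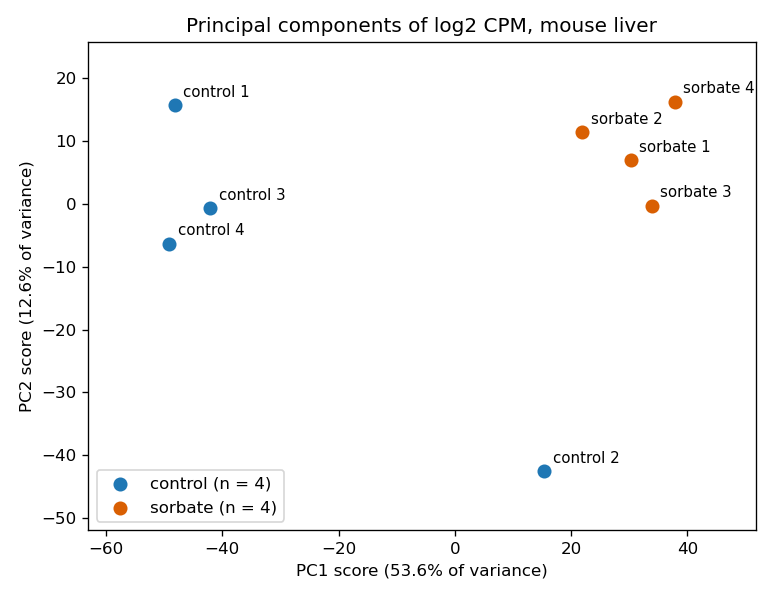
Scores of the 8 libraries on the first 2 principal components of log2 CPM, with the percentage of variance on each axis; each point is 1 library, coloured by group. Control 2 has a PC1 score of 15.4, next to the sorbate libraries (21.9 to 37.8), while the other controls lie between −49.1 and −42.1.

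Among the 10 largest rises were genes of the circadian clock and its outputs. Usp2 (ENSMUSG00000032010, chromosome 9, 44067021 to 44095627), a rhythmically expressed deubiquitinase, rose from 2.80 ± 0.260 to 46.2 ± 5.61 CPM (SD, n = 4 per group; log2 fold change 4.04, SE 0.14, adjusted p = 1.615e-07). Wee1, a cell cycle kinase under clock control, rose by 3.79 on the log2 scale (SE 0.35), Per3 by 3.19 (SE 0.46), Dbp, a clock-output transcription factor, by 3.16 (SE 0.53), and Ciart, a repressor within the clock, by 3.05 (SE 0.32). Arntl, which encodes the activator BMAL1 (chromosome 7), went the other way and fell from 13.5 ± 3.07 to 1.03 ± 0.187 CPM (log2 fold change −3.71, SE 0.22, adjusted p = 3.599e-05). Its close partner Npas2 fell by 4.00 on the log2 scale (SE 0.63). Per2 rose from 10.7 ± 1.39 to 39.1 ± 7.83 CPM. Of the 24 clock genes tested, 15 rose and 5 fell (16 and 5 adjusted over the list alone), with a median log2 fold change of 0.99. The camera test placed the list higher (adjusted p = 1.72e-14), and adjusted p = 0.139 with an estimated correlation. Nr1d1, a clock repressor chosen after its value was seen, stood at 54.2 ± 10.2 and 54.7 ± 21.5 CPM and did not pass the test (adjusted p = 0.976). Control 2 had 2.90 CPM of Usp2, within the 2.49 to 3.09 CPM of the other controls, but 33.3 CPM of Dbp against 4.53 to 8.76 CPM in the other controls. Without control 2 the log2 fold change of Dbp was 4.14 and that of Per3 4.03, and with the surrogate variable they were 2.56 and 2.53.

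**Figure D2:**
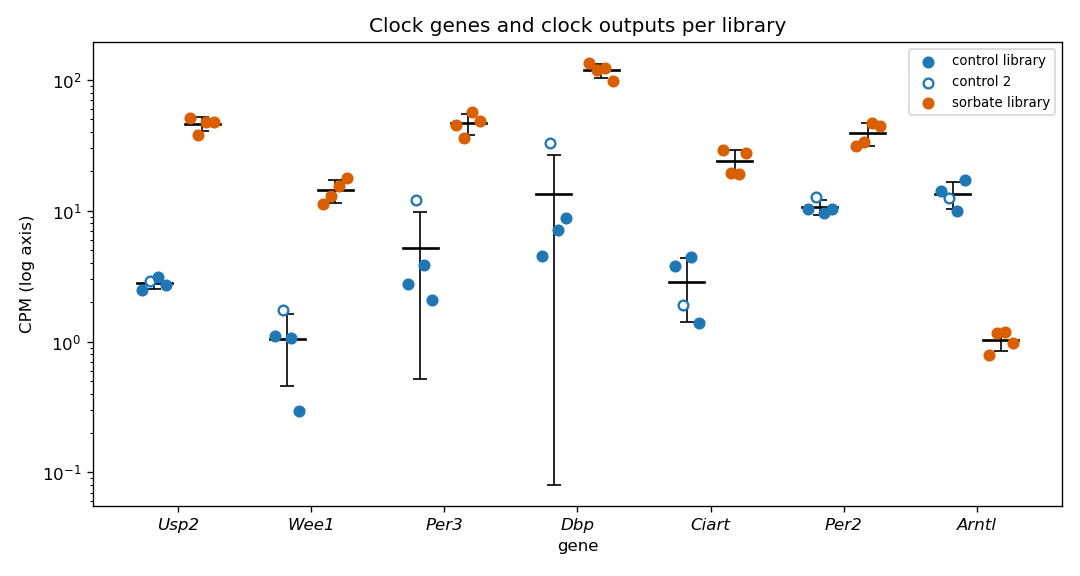
CPM on a log axis of 7 clock genes and clock outputs in each of the 8 libraries; points are libraries, open points are control 2, and black bars give the mean ± SD of 4 libraries per group. In every gene shown the 4 sorbate libraries lie outside the range of the 4 controls, above it for 6 genes and below it for Arntl.

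Genes of fatty acid oxidation and acyl-CoA handling rose. Cyp4a10, a fatty acid hydroxylase under control of the nuclear receptor PPAR-alpha (ENSMUSG00000066072, chromosome 4, 115518264 to 115533649), rose from 5.85 ± 1.81 to 95.5 ± 50.5 CPM (log2 fold change 4.03, SE 0.40, adjusted p = 6.079e-04). The acyl-CoA thioesterases Acot3, Acot1 and Acot4 rose by 3.94 (SE 0.61), 3.54 (SE 0.29) and 1.94 (SE 0.17) on the log2 scale. Acot1, Acot3 and the Cyp4a genes have close paralogs that may share reads. Smaller rises were measured for the mitochondrial enzymes Cpt2 (0.77, SE 0.11), Acadl (0.72, SE 0.10) and Acadm (0.69, SE 0.12). Of the 43 PPAR-alpha targets tested 29 rose and 0 fell (32 and 0 adjusted over the list alone), with a median log2 fold change of 0.69 (camera adjusted p = 7.71e-20, and adjusted p = 0.225 with an estimated correlation). Of 24 genes of short- and medium-chain acyl-CoA handling, 12 rose and 1 fell (14 and 2 adjusted over the list alone; adjusted p = 1.75e-08, and adjusted p = 0.225 with an estimated correlation), among the former Acsl1 (1.63, SE 0.28) and the carnitine transporter Slc22a5 (1.19, SE 0.14). This acyl-CoA list is broader than its name, since Acsl1 encodes a long-chain acyl-CoA synthetase. It also shares Acads and Acadm with the PPAR-alpha list, so the 2 lists are not separate results. Of 7 ketone body genes 1 rose and 2 fell (2 and 2 adjusted over the list alone). The transporters Slc16a6 and Slc16a1 had log2 fold changes of −1.84 (SE 0.26) and −1.40 (SE 0.24), and of −1.26 and −0.83 with the surrogate variable. The list median was 0.25 and the mean and the camera direction were negative (adjusted p = 0.989).

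Cholesterol synthesis genes fell. Of 23 genes of the pathway and other targets of the transcription factor SREBP2, 19 fell and 0 rose (20 and 0 adjusted over the list alone), with a median log2 fold change of −1.48 (camera adjusted p = 2.2e-30, and adjusted p = 0.139 with an estimated correlation). Squalene epoxidase, Sqle, fell from 85.3 ± 40.2 to 5.65 ± 1.66 CPM (log2 fold change −3.91, SE 0.43, adjusted p = 8.572e-04; −2.78 with the surrogate variable). Idi1 (−2.97, SE 0.29) and Hmgcs1 (−2.61, SE 0.27) of the same pathway also fell, as did Insig1, a feedback regulator (−1.31, SE 0.13). The score of this list, the mean log2 CPM of its members, was 5.34 in control 2 against 6.13 to 6.18 in the other controls and 4.25 to 4.67 with sorbate. The cholesterol exporters Abcg5 and Abcg8 rose by 1.46 (SE 0.20) and 1.57 (SE 0.24), within a list of 21 LXR targets and lipoprotein genes of which 4 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.0764). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose from 10.3 ± 6.04 to 67.2 ± 33.7 CPM (log2 fold change 2.71, SE 0.53, adjusted p = 0.0111), and its call was lost with the surrogate variable (log2 fold change 2.37, adjusted p = 0.0908). Of 23 bile acid genes 5 rose and 1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.054). Of 29 lipogenic genes 4 rose and 7 fell (4 and 12 adjusted over the list alone; camera adjusted p = 0.0764). Srebf1, a lipogenic transcription factor, rose by 1.03 (SE 0.22), a call lost with the surrogate variable (log2 fold change 0.76, adjusted p = 0.0506), and G6pdx fell by 2.18 (SE 0.36; −1.41 with the surrogate variable).

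Acute-phase genes, which the liver raises in response to inflammatory cytokines, were lower with sorbate. Saa2 and Saa1, which encode serum amyloid A proteins on chromosome 7 (46751790 to 46754313 and 46740497 to 46742980), fell by 8.12 (SE 0.94, adjusted p = 0.00115) and 5.82 (SE 0.63, adjusted p = 8.454e-04) on the log2 scale. Saa1 averaged 10849 ± 7007 CPM in the controls and 191.9 ± 54.0 CPM with sorbate (SD, n = 4 per group). These paralogs may share reads, and their values are uncertain one by one. Lcn2, an iron-siderophore binding protein, fell by 7.02 (SE 1.03), Orm2 by 5.33 (SE 0.77) and Apcs, which encodes serum amyloid P, by 4.47 (SE 0.66), while the fibrinogen gene Fgg fell by 1.82 (SE 0.26). Of the 30 genes of this list 22 fell and 0 rose (26 and 0 adjusted over the list alone), with a median of −1.79 (camera adjusted p = 4.29e-21, and adjusted p = 0.225 with an estimated correlation). The controls were uneven. Saa1 and Saa2 together took 2.15%, 2.15% and 3.41% of the counts in controls 1, 3 and 4, 0.277% in control 2, and 0.0134% to 0.0313% in the sorbate libraries. Control 2 lay above every sorbate library in the 6 genes named above. The naming rule required this of the genes taken as largest falls, so for them it lends no support. Leaving out any 1 library kept the calls of all 6 genes, and the fall of Apcs was 3.80 without control 4. With the surrogate variable the log2 fold change was −5.80 for Saa2, −4.20 for Saa1, −3.67 for Lcn2, −2.81 for Orm2 and −2.53 for Apcs.

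**Figure D3:**
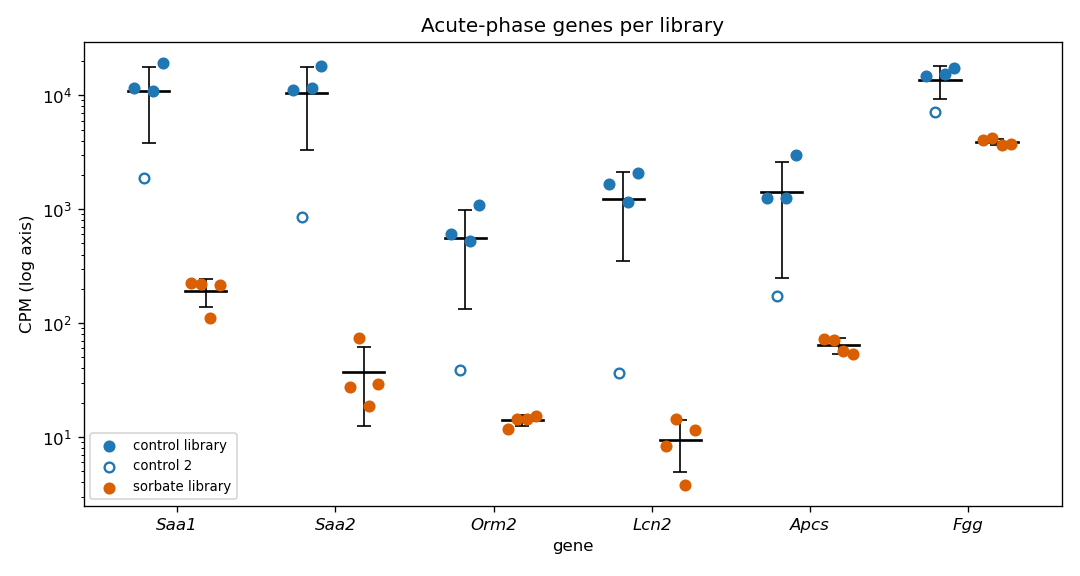
CPM on a log axis of 6 acute-phase genes in each of the 8 libraries; points are libraries, open points are control 2, and black bars give the mean ± SD of 4 libraries per group. Control 2 lies between the other controls and the sorbate libraries, for Saa1 at 1896 CPM against 10940 to 19012 CPM in the other controls and 111.1 to 223.2 CPM with sorbate.

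Of the inflammation genes named in advance and tested, only the serum amyloids showed a called change. Il1b averaged 2.47 ± 0.535 and 2.47 ± 1.57 CPM (log2 fold change −0.01, SE 0.44, adjusted p = 0.994). Ccl2 had a log2 fold change of −0.57 (SE 0.51, adjusted p = 0.478) on 59 and 44 counts in all, and Nfkbia one of 0.36 (SE 0.20, adjusted p = 0.244). Over the leave-outs Ccl2 ran from −1.19 (without sorbate 2) to −0.30 (without sorbate 1). Nfkbia ran from 0.11 (without sorbate 4) to 0.47 (without sorbate 3). Tnf (7 counts over the 4 controls, 10 over the 4 sorbate libraries) and Il6 (3 and 2 counts) were too low to be tested, so a difference was not detectable at this depth. Of the 24 tested genes of the NF-kB list, which holds cytokines, chemokines and other NF-kB-driven genes, 3 fell and 0 rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.1). These were the neutrophil chemoattractant Cxcl1 (from 110.0 ± 69.0 to 8.73 ± 1.77 CPM; log2 fold change −3.65, SE 0.61, adjusted p = 0.00561), Cxcl2 and Icam1. With the surrogate variable the log2 fold change of Cxcl1 was −1.62. The score of the NF-kB list was 2.467 in control 2, 2.736 to 2.989 in the other controls and 2.307 to 2.6 with sorbate. The call of Icam1 was lost when any library but control 2 was left out (log2 fold change −1.60 to −1.12, adjusted p up to 0.0628) and that of Cxcl2 in 6 of the 8 leave-outs (−2.08 to −1.43, adjusted p up to 0.108), and both with the surrogate variable (log2 fold changes −0.50 and −1.44, adjusted p = 0.137 and 0.191). Of 24 innate immune receptor and inflammasome genes 4 fell and 1 rose (7 and 2 adjusted over the list alone). The fall of Il1r1 held in all 8 leave-outs (−1.54, SE 0.32) but not with the surrogate variable (−0.85, adjusted p = 0.06), while those of Tlr2 and Tnfrsf1a and the rise of the flagellin receptor Tlr5 did not (adjusted p up to 0.0759, 0.0898 and 0.0743; log2 fold changes over the leave-outs −2.26 to −1.43, −1.39 to −0.889 and 1.49 to 2.35). With the surrogate variable these 3 had log2 fold changes of −0.68, −0.29 and 1.28 and were not called (adjusted p of 0.261, 0.333 and 0.0596). The list was called lower (adjusted p = 0.0413, and adjusted p = 0.462 with an estimated correlation), and the call was lost without control 1, control 3, control 4, sorbate 1, sorbate 3 or sorbate 4 (adjusted p from 0.055 to 0.0775). The score of this list was 2.87 in control 2, 3.48 to 3.62 in the other controls and 2.82 to 3.19 with sorbate. Markers of Kupffer cells, monocytes and neutrophils, described below, were lower as well (median log2 fold changes −0.93, −1.03 and −3.16) and low in control 2, and whether the fall of the receptor genes reflects these cells was not tested. Of 33 type I interferon genes 3 rose and 2 fell (3 and 3 adjusted over the list alone; adjusted p = 0.505), the latter including Ifi47 (−1.06, SE 0.14).

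The class I deacetylase genes were measured without a called change at the threshold of 0.05. Log2 fold changes were −0.23 for Hdac1 (SE 0.10, adjusted p = 0.148), −0.16 for Hdac2 (SE 0.11, adjusted p = 0.357), 0.31 for Hdac3 (SE 0.11, adjusted p = 0.0957) and 0.00 for Hdac8 (SE 0.17, adjusted p = 0.996). Hdac3 passed the looser threshold of 0.1, and its log2 fold change was 0.40 without control 2 and 0.20 with the surrogate variable. Of 26 genes of class I HDACs and their corepressor partners 3 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.73). Chd3, a remodeller in an HDAC complex, rose by 0.55 (SE 0.11), and Tbl1xr1 fell by 0.64 (SE 0.13), both calls being lost with the surrogate variable (log2 fold changes 0.46 and −0.41, adjusted p = 0.0633 and 0.0589). The list median was −0.02, the mean and the test direction were positive, and the median was 0.10 with library size alone. Of 26 other deacylases and acyltransferases 1 rose and 0 fell (0 and 0 adjusted over the list alone; adjusted p = 0.173). This was Kat2a (0.42, SE 0.11, adjusted p = 0.0311), whose call was lost in 6 of the 8 leave-outs (log2 fold change 0.379 to 0.475 over all 8, adjusted p up to 0.0871) and with the surrogate variable (0.46, adjusted p = 0.0737). Of 17 genes known to be raised by HDAC inhibitors 1 rose and 3 fell (1 and 3 adjusted over the list alone; adjusted p = 0.518). Txnip rose by 1.56 (SE 0.29), while Cdkn1a, the cell cycle inhibitor p21, fell from 64.5 ± 42.3 to 1.67 ± 0.736 CPM (log2 fold change −5.25, SE 0.74). Cdkn1a stood at 6.31 CPM in control 2 and at 68.5 to 107.5 CPM in the other controls, and its log2 fold change was −3.02 with the surrogate variable. The score of the HDAC inhibitor list was 2.954 in control 2, below the 3.36 to 3.984 of the sorbate libraries and the 4.552 to 4.686 of the other controls. In that list the metallothioneins Mt1 and Mt2 had log2 fold changes of −3.38 (SE 0.93) and −3.93 (SE 1.03). Their calls were lost when any library but control 2 was left out (log2 fold changes −3.78 to −3.15 and −4.33 to −3.65 over the 8 leave-outs, adjusted p up to 0.104 and 0.0918), and with the surrogate variable their values were 0.72 and 0.57 (adjusted p = 0.317 and 0.464).

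Genes of detoxification and amino acid metabolism rose in part. Nr1i3, which encodes the xenobiotic receptor CAR, rose from 59.9 ± 12.7 to 233.1 ± 43.9 CPM (log2 fold change 1.96, SE 0.18, adjusted p = 3.498e-04), and Por, the electron donor of cytochrome P450 enzymes, rose by 1.58 (SE 0.22). Of 31 targets of CAR and PXR 8 rose and 1 fell (12 and 2 adjusted over the list alone; camera adjusted p = 7.42e-06, and adjusted p = 0.225 with an estimated correlation). Of 33 genes of the urea cycle and amino acid catabolism 10 rose and 2 fell (17 and 2 adjusted over the list alone; adjusted p = 2.13e-04, and adjusted p = 0.462 with an estimated correlation), with rises of Asl (1.14, SE 0.14) and Hpd (0.88, SE 0.14) and a fall of Bhmt (−0.80, SE 0.14). Of 26 genes of gluconeogenesis and the fasting response 6 rose and 2 fell (8 and 2 adjusted over the list alone; adjusted p = 0.00481, and adjusted p = 0.341 with an estimated correlation), Gpt (0.81, SE 0.14) and Gpt2 (0.76, SE 0.14) among the former. Of 24 glycolysis and glycogen genes 1 rose and 2 fell (1 and 2 adjusted over the list alone; adjusted p = 0.957), and Gys2, the liver glycogen synthase, rose by 1.87 (SE 0.24). The median of this list was −0.02, its mean and test direction were positive, and its median was 0.10 with library size alone. Of 7 targets of the aryl hydrocarbon receptor 2 rose and 1 fell (2 and 2 adjusted over the list alone; adjusted p = 0.409), with a median of −0.02 that was 0.10 with library size alone and a positive test direction. Of 30 NRF2 and oxidative stress genes 4 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.495), Nfe2l2 among the former (0.76, SE 0.12).

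Stress and growth lists were lower or not called. Of 24 genes of the unfolded protein response 8 fell and 0 rose (12 and 0 adjusted over the list alone; camera adjusted p = 5e-05, and adjusted p = 0.462 with an estimated correlation), such as Sdf2l1 (−1.31, SE 0.25) and Pdia4 (−0.67, SE 0.12). Of 33 cytosolic ribosomal protein genes 4 fell and 0 rose (19 and 0 adjusted over the list alone; adjusted p = 4.52e-07, and adjusted p = 0.492 with an estimated correlation), with a median of −0.39. The calls of these 4, Rpl23, Rpl3, Rplp1 and Rps16, were each lost in 4 to 7 leave-outs (log2 fold changes −0.61 to −0.34, adjusted p up to 0.143). All 4 calls were also lost with the surrogate variable (log2 fold changes −0.43 to −0.37) and with library size alone, where the list median was −0.25. Of 20 heat shock genes 2 fell (3 adjusted over the list alone; adjusted p = 0.0118, and adjusted p = 0.592 with an estimated correlation), a call lost without control 1 (adjusted p = 0.0775). The 2 genes were Hsp90aa1 (−0.98) and Chordc1 (−0.50), whose calls were lost in 2 and 7 leave-outs and with the surrogate variable. Of 29 cell cycle genes 3 fell and 1 rose (6 and 1 adjusted over the list alone; adjusted p = 0.0328, and adjusted p = 0.592 with an estimated correlation), a call lost without control 1, sorbate 3 or sorbate 4 (adjusted p of 0.0775, 0.0557 and 0.104). The falls of Mcm3, Mcm4 and Mcm5 and the rise of Ccne2 were each lost in 5 to 7 leave-outs (adjusted p up to 0.14) and with the surrogate variable. Of 21 p53 targets 3 fell (4 adjusted over the list alone; adjusted p = 0.0328, and adjusted p = 0.462 with an estimated correlation), a call lost without control 3 or sorbate 4 (adjusted p of 0.0518 and 0.0568). The list of ATF4 targets (4 fell and 1 rose of 26, 6 and 1 adjusted over the list alone; adjusted p = 0.0506) included Asns, which fell by 2.18 (SE 0.37). Control 2 lay within the range of the sorbate scores in the unfolded protein response (6.92; other controls 7.28 to 7.36, sorbate 6.48 to 6.96), heat shock (5.26; 5.65 to 5.98, 5.09 to 5.52), cell cycle (0.919; 1.327 to 1.504, 0.375 to 1.368), p53 (3.04; 3.38 to 3.52, 2.73 to 3.08) and ATF4 lists (2.95; 3.55 to 3.58, 2.85 to 3.23). The glucocorticoid-responsive list had 5 falls of 20 members (5 falls and 2 rises adjusted over the list alone; adjusted p = 0.0803). Here too control 2 lay within the sorbate scores (5.541; other controls 6.639 to 6.992, sorbate 5.193 to 5.855). Of 22 immediate early genes 3 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.317), and Klf10 rose by 1.23 (SE 0.15). Of 22 male-biased liver genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.124), the latter being Elovl3 (−1.58, SE 0.30). Of 21 potassium and sodium transport genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.245), the latter being Nedd4l (−1.55, SE 0.22). No member passed among 32 nuclear genes of oxidative phosphorylation in edgeR (8 at an unadjusted p under 0.05, 7 called by DESeq2 and 0 by limma-voom; camera adjusted p = 0.0875). Among 13 mitochondrially encoded transcripts 0 were called by edgeR, DESeq2 or limma-voom and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.394).

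Markers of macrophages and blood were lower with sorbate, and so were 3 of 4 neutrophil markers, with the limits given below. Of 15 Kupffer cell markers, which label the resident macrophages of the liver, 8 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of −0.93 (camera adjusted p = 8.11e-05, and adjusted p = 0.623 with an estimated correlation). Cd163 (−1.30, SE 0.31), Timd4 (−1.06, SE 0.25) and Vsig4 (−1.04, SE 0.27) were among the falls, each lost in 6 of the 8 leave-outs (log2 fold changes −1.55 to −1.19, −1.28 to −0.906 and −1.24 to −0.877 over all 8, adjusted p up to 0.0788, 0.0716 and 0.102) and with the surrogate variable (log2 fold changes −0.46, −0.72 and −0.53, adjusted p = 0.192, 0.12 and 0.266), while the iron exporter Slc40a1 rose by 0.90 (SE 0.16). The score of this list was 4.17 in control 2 and 4.94 to 5.29 in the other controls, against 3.70 to 4.57 with sorbate. Of 10 monocyte markers 2 fell (3 adjusted over the list alone; adjusted p = 0.00167, and adjusted p = 0.623 with an estimated correlation), among them Spp1 (−2.16, SE 0.39; −1.25 with the surrogate variable). Spp1 is also a member of the cholangiocyte list. The other fall was that of Plac8 (log2 fold change −1.39), a call lost in 6 of the 8 leave-outs (adjusted p up to 0.104). It was also lost in robust edgeR and with the surrogate variable (log2 fold change −0.67, adjusted p = 0.259). The monocyte score was 0.795 in control 2, 2.02 to 2.43 in the other controls and 0.653 to 1.56 with sorbate. Of 7 erythroid markers 6 fell and 0 rose (6 and 1 adjusted over the list alone; adjusted p = 0.00167, and adjusted p = 0.623 with an estimated correlation), including the haemoglobin gene Hbb-bt (−2.18, SE 0.45), whose call was lost with the surrogate variable (log2 fold change −1.21, adjusted p = 0.0954). The erythroid score was 4.63 in control 2, 5.36 to 6.64 in the other controls and 3.93 to 4.62 with sorbate. Of the 4 neutrophil markers high enough to be tested, too few for a list test, 3 fell. These were S100a9, Csf3r and Lcn2, the last of which is also counted among the acute-phase genes. The call of Csf3r (log2 fold change −1.40) was lost when any library but control 2 was left out, with library size alone and in limma-voom. It was also lost with the surrogate variable (−0.52, adjusted p = 0.433). S100a9 went from 7.07 ± 5.01 to 0.228 ± 0.264 CPM (log2 fold change −4.92, SE 0.98, adjusted p = 0.0112), a call lost with the surrogate variable (log2 fold change −1.64, adjusted p = 0.252) and in limma-voom. Its log2 fold change was −6.16 without sorbate 2. Prtn3, a granulocyte protease, fell by 6.17 (SE 0.97) and by 7.07 without sorbate 4, with −3.51 under the surrogate variable, and was not called in limma-voom. The score of the 4 neutrophil markers, Lcn2 among them, was 0.158 in control 2, 3.49 to 4.27 in the other controls and −0.697 to 0.859 with sorbate.

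Other cell type lists were not called. Of 16 stellate cell markers 0 were called by edgeR, DESeq2 or limma-voom and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.76). Of 17 endothelial markers 1 fell and 0 rose (0 and 0 adjusted over the list alone; adjusted p = 0.0528). Of 14 periportal hepatocyte markers 1 rose and 2 fell (3 and 3 adjusted over the list alone; adjusted p = 0.546), and of 16 pericentral markers 4 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.298). Cyp2a5, in a family of close paralogs, rose from 70.8 ± 36.1 to 517.4 ± 83.0 CPM (log2 fold change 2.87, SE 0.31). Of 8 cholangiocyte markers 2 fell (2 adjusted over the list alone; adjusted p = 0.477), with a median of 0.06 and a negative mean and test direction. Of 5 B and plasma cell markers 1 fell (1 adjusted over the list alone; adjusted p = 0.298). Too few members were measured for a test of T and NK cells (4 members), pancreatic acinar cells (2 members) and adipocytes (3 members), where 0 were called by edgeR, DESeq2 or limma-voom and 0 had an unadjusted p under 0.05. Of 3 gut and mesothelial markers, also too few, 1 rose, which was Fabp2 (0.73, SE 0.20), a call lost when any library but control 2 was left out (log2 fold change 0.487 to 0.845 over the 8 leave-outs, adjusted p up to 0.118) and with the surrogate variable (0.72, adjusted p = 0.123). In the gut and the pancreatic lists the median was negative and the test direction positive, and the pancreatic median was 0.08 with library size alone.

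The other genes with the largest changes belong to none of these themes as a group. Nrep (chromosome 18, 33437019 to 33464029) rose from 8.48 ± 4.99 to 64.6 ± 19.2 CPM (log2 fold change 2.93, SE 0.39, adjusted p = 0.00212). The keratin gene Krt23 rose by 3.10 (SE 0.69), by 4.92 without control 2, and lost its call without control 3, control 4 or sorbate 3 (log2 fold change at least 2.74 in all leave-outs, adjusted p up to 0.0629). Apol10b fell by 4.45 (SE 0.69), and Dnajc12, a co-chaperone, fell from 80.4 ± 53.5 to 5.16 ± 0.817 CPM (log2 fold change −3.96, SE 0.60, adjusted p = 0.00364). Dnajc12 stood at 10.6 CPM in control 2 and at 84.1 to 140.8 CPM in the other controls. With the surrogate variable the log2 fold changes were −2.10 for Dnajc12 and −2.99 for Apol10b.

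**Figure D4:**
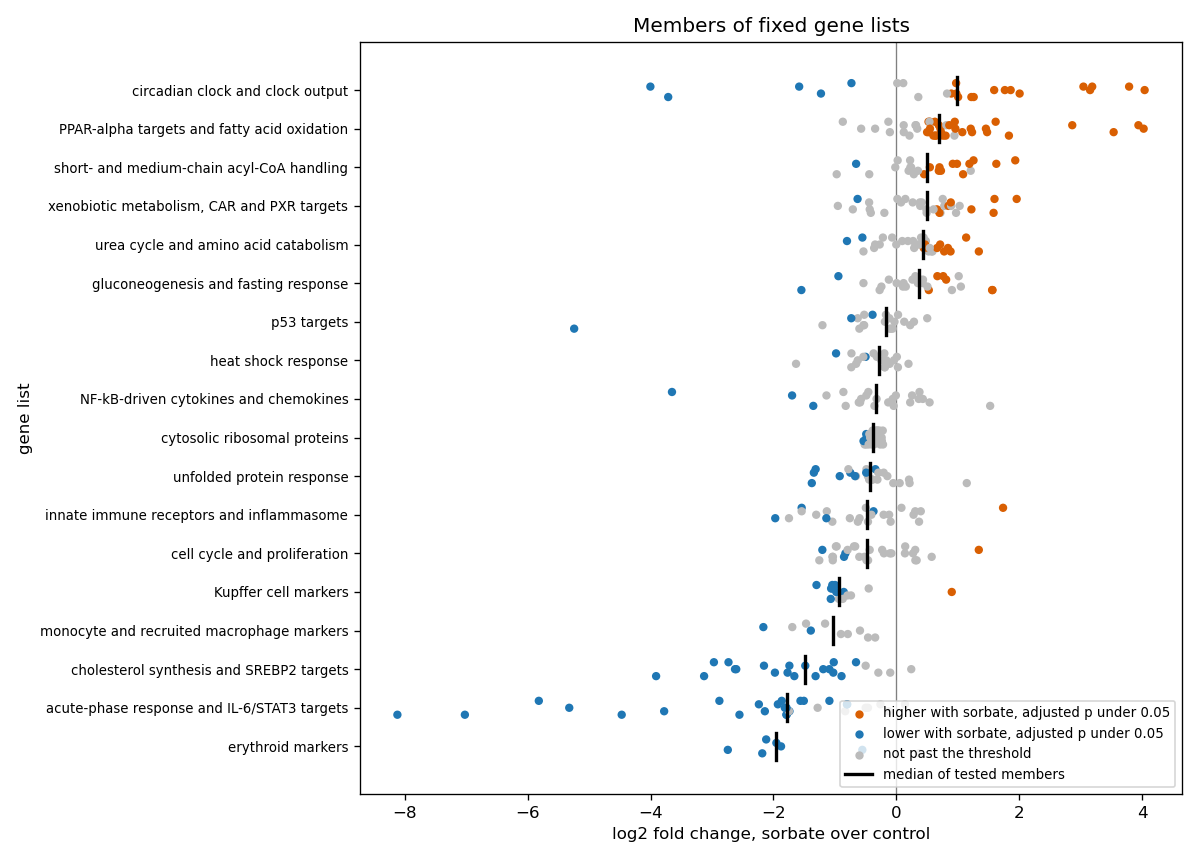
Log2 fold change (sorbate over control) of each tested member of the 17 lists called by camera and of the cytokine list; orange and blue points passed the gene test, grey points did not, and black lines are list medians. Medians run from −1.95 for erythroid markers to 0.99 for clock genes, and all 17 calls have an adjusted p of at least 0.139 with an estimated correlation.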

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

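The tests on other splits of the libraries were chosen before their results were seen, and the tests on clock phase, scaling, library positions, stellate markers and haemoglobins were chosen only after the patterns were seen. In 144 groups of 4 values, 12 had a library farther from the rest than Dixon's 95% critical value allows, where chance gives about 7. Of these, 7 concern control 2. Its list score (mean log2 CPM) was 5.344 for cholesterol synthesis (6.133 to 6.179 in the other controls), 2.95 for ATF4 targets (3.55 to 3.584) and 2.954 for genes raised by HDAC inhibitors (4.552 to 4.686). Its log2 CPM was 2.68 for Cdkn1a (6.099 to 6.749), 5.191 for Lcn2 (10.17 to 11.03), 0.9967 for Prtn3 (5.339 to 5.935) and 9.726 for Saa2 (13.45 to 14.15). Control 4 had the lowest scores for PPAR-alpha targets (5.639, others 5.807 to 5.83) and gluconeogenesis (6.169, others 6.341 to 6.368). Sorbate 2 had the highest scores of its group for innate immune receptors (3.189, others 2.817 to 2.881) and monocyte markers (1.564, others 0.6525 to 0.7831), and sorbate 3 the lowest log2 CPM of Saa1 (6.797, others 7.742 to 7.803).

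Chance is an unlikely source of the number of changed genes: of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave 1656 genes or more, and the highest of the others gave 218. It is not excluded, since 1 of 35 is the smallest share possible. The other splits also hold the group difference within their sides, which lowers their counts. No split can tell the treatment from a batch or hour that runs with the group. For the number of lists called by camera with the preset correlation chance remains possible, since 10 of the 35 splits called at least as many as the real 17 and the highest of the others called 22. The split with 218 genes and 22 lists sets controls 1, 3 and 4 with sorbate 2 against control 2 with sorbate 1, 3 and 4.

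The clock genes parted by phase. A phase was given to 18 of the 24 tested clock genes after their values were seen, and the other 6, of which 4 rose and 1 fell, were left out. Across 13 clock genes whose liver peak textbook knowledge places near dusk the median log2 fold change was 1.86 and 11 were higher, and across 5 placed near dawn it was −1.23 and 4 were lower, a difference of 3.089. The tables argue against the scaling of the libraries as the cause. Scaling moves all genes of a library alike, while 15 clock genes rose and 5 fell. With library size alone the median of all genes moved only from −0.02 to 0.11, and 20 of the 20 called clock genes stayed called. When 1 library was left out 16 to 20 stayed called, which does not test the scaling. A candidate explanation that stays open is that the livers of the groups were collected at different clock hours, which would part the dusk and dawn genes in this way, but the labels give no hour and the hour cannot be separated from the group. An action of sorbate on the clock or on feeding could also part these genes and was not tested. The unknown hour limits every comparison of the groups, not only that of the clock genes. It also covers the genes of fatty acid oxidation, cholesterol and bile acid synthesis and detoxification, where its share was not tested.

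The acute-phase difference rests on uneven controls. A wrong label on a sorbate liver is argued against by the clock genes called without control 2: on a scale from 0 (the other controls) to 1 (sorbate) the median position of this library over 20 such genes was 0.15, although it was 0.828 over 26 acute-phase genes. Sorbate RNA mixed into the library is argued against by the same comparison on linear CPM, where the positions differed by 0.862 when a mixture needs them to be alike, while a swap with a sample outside these groups stays open. Whether an inflammatory response of the water-treated mice that sorbate did not cause accounts for part of the fall cannot be told apart from an effect of sorbate, since no mice without gavage were analysed here. The acute-phase score varied with an SD of 0.945 among the controls and 0.032 among the sorbate livers. Most of the former comes from control 2, without which the SD of the controls was 0.211.

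Kupffer cell and erythroid markers were called lower by camera, with adjusted p = 0.623 for both lists at an estimated correlation and 0.184 with fry. Control 2, with a Kupffer score of 4.17, lay within the 3.699 to 4.57 of the sorbate livers. Against an equal fall of all non-hepatocyte cells the stellate cell markers give limited evidence. The Kupffer score minus the stellate score differed between the groups by −0.807 (exact permutation p = 0.0286, the smallest that 70 arrangements allow). The stellate list was chosen for this after its values were seen, and the p does not allow for that choice. Endothelial markers had a median log2 fold change of −0.26 (camera adjusted p = 0.0528), so a fall shared by some of these cells stays open. Control 2 had the lowest control score for Kupffer, endothelial (3.027) and stellate markers (2.967) alike. For the erythroid part, less residual blood in the sorbate livers is a candidate explanation that stays open, as the 4 haemoglobin genes, which have close paralogs, had log2 fold changes within 0.306 of each other. Fewer Kupffer cells and less RNA per Kupffer cell were not tested, and an effect of sorbate stays open.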

How the results depend on the processing

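Removal of the trends with exon length and GC content was the only alternative chosen after seeing the data. The counts of 818 higher and 838 lower genes stayed within 1.5 times under DESeq2's size factors, upper-quartile scaling, both filters, the DESeq2 Wald test, limma-voom, robust edgeR, without the 10 most abundant genes and with exon length and GC trends removed, from 717 to 1193 higher and from 711 to 1244 lower. They moved to 1300 and 550 with library size alone, to 1968 and 1944 with sample quality weights, to 313 and 293 with 1 surrogate variable, to 1337 and 1414 at an adjusted p under 0.1 and to 80 and 122 against a 1.5-fold change. The last 2 follow from their construction. Library size alone leaves out the TMM factors, which were 0.92 to 1.01 in the controls and 1.03 to 1.07 with sorbate. Leaving them out raises the log2 fold changes of all genes, and their median moved from −0.02 to 0.11. For the sample quality weights and the surrogate variable the cause was not tested. Leaving out 1 library gave 332 to 2053 higher and 357 to 1915 lower genes, the highest without control 2, where 818 of the higher and 836 of the lower genes were shared with the full set; the other 7 leave-outs, with as many samples as that one, gave fewer calls than the full set. Of 142 named genes past the threshold 81 were called in all 8 leave-outs and 66 were tested and called under every alternative apart from the 1.5-fold test, and with the surrogate variable, which correlates with the group (0.588), 69 lost their call. Of the named genes not past the threshold, 13 were called without control 2 and 12 with sample quality weights.

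List calls (6 higher, 8 lower, 3 lower cell type lists) went to 0, 0 and 0 with an estimated correlation, to 7, 2 and 0 with fry and to 10, 11 and 5 without a filter on low counts, and were the same 17 lists with DESeq2's size factors. Leave-outs gave 5 to 12 lower lists and 3 to 6 lower cell type lists. The cause was not tested. Values near 0 changed sign. Hdac8 had log2 fold changes of −0.0326 with upper-quartile scaling, −0.0013 with the stricter filter, −0.0408 with the surrogate variable and −0.0708 to 0.0619 over the leave-outs. Il1b had 0.1252 with library size alone, 5e-04 without a filter, 0.0036 with DESeq2, 0.2327 with the surrogate variable, 0.0492 with the trends removed and −0.4305 to 0.3094 over the leave-outs. With the surrogate variable Cela1 had −0.1092, Mt1 0.7177 and Mt2 0.5742, and the cause was not tested. The direction of the list test turned in some leave-outs for ketone body genes (median 0.1594 to 0.3065), glycolysis (−0.1247 to 0.0459) and stellate markers (−0.0801 to 0.2438). The difference in total count ran from −1330404 to 2026529, that in mitochondrial share from −0.0874 to 0.936 points and that in the share of the 10 most abundant genes from −1.30 to −0.714 points over the leave-outs, and the share of the 50 most abundant genes differed by −4.899 points. Depth limits the low genes: Tnf and Il6 had at most 10 counts per group. Simulated 1.5-fold changes were called in 10.8% of cases, but those genes were drawn from all expression levels and depth was not varied.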

Other observations

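The position of a library between its own group (0) and the other group (1), over genes called without that library, was a measure chosen only after the data were seen. For control 2 it differed between gene groups. Its median was 0.15 for 20 clock genes and 0.23 for 32 PPAR-alpha targets, 0.469 for 21 cholesterol synthesis genes, and 0.767, 0.828 and 0.963 for 7 erythroid markers, 26 acute-phase genes and 14 Kupffer cell markers. Over all 3895 called genes tested in both fits it was 0.745. For the other controls the median over all such genes lay between −0.147 and 0.001, and for the sorbate libraries between −0.067 and 0.196. These rest on other and fewer genes, 684 to 1102 per library. Control 2 also entered their fits and group means, so they are not directly comparable with the value of control 2. Other libraries also differed between gene groups: sorbate 2 had a median of 0.597 for 9 Kupffer cell markers, and control 4 one of −0.555 for 19 acute-phase genes. The PPAR-alpha score was 5.807 in control 2, within 5.639 to 5.83 of the other controls, and 6.27 to 7.026 with sorbate.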
